A study of Mus musculus with 14 samples.

How the data were processed

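The study mapped meiotic DNA breaks in testis of C57BL/6N mice by immunoprecipitation of DMC1, the recombinase that coats the single-stranded ends of broken meiotic DNA, followed by single-stranded DNA sequencing. The 8 DMC1 libraries came from mice aged 8 weeks: 3 wild-type, 2 Stag3-/-, 2 Rec8-/- and 1 Stag3-/-Rec8-/- library. STAG3 and REC8 are subunits of the meiosis-specific cohesin that builds chromosome axes. The 5 input libraries of the series have no peak list of their own and were used only through the control that some of the DMC1 lists were called against. Lists of H3K4me3 peaks for wild-type B6 (a re-analysis of an earlier sample) and for spermatocytes of a Prdm9 mutant at 14 days after birth were used as reference sets. PRDM9 is the methyltransferase that places H3K4me3 at recombination hotspots. The sample of this mutant is titled as a knockout, whereas its description gives a glutamate-to-lysine substitution that leaves a severely hypomorphic enzyme, and it is called the Prdm9 mutant here.

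Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32 and aligned with BWA 0.5.10 to mm10, and MACS2 2.0 and bedtools were used. The headers of the DMC1 lists name MACS2 2.1.0.20140616 instead. Each list was called on 1 library, not on pooled libraries, with a fragment length of 800 bp, per the file headers. The deposited columns used here were the pileup signal at the summit, the −log10 p and −log10 q of each peak, and the fold enrichment of each peak over its local background, as the authors' peak caller gave them. These values belong to single peaks of single lists and served only to rank and filter peaks within a list.

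The lists fell into 2 processing batches of 4 libraries, per the file headers. Wild-type 1 and 2 and both Stag3-/- lists were called without an input control, at a p cutoff of 0.01, on alignments whose names mark removed duplicates, from 403957, 387275, 1101653 and 822833 tags. Wild-type 3, both Rec8-/- lists and the double mutant list were called against an input of 12999146 to 21369617 tags, at a q cutoff of 0.01, on alignments not marked so, from 5069031, 4967736, 6429397 and 5837590 tags. Wild-type libraries stand in both batches. Stag3-/- and Rec8-/- do not meet in 1 batch, so a direct contrast of the single mutants is confounded with processing.

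The H3K4me3 lists carry a peak score of the authors' peak caller, and the deposited hotspot lists also carry a hotspot score, whose unit is not given in the sources used here. The note deposited with the wild-type lists states that uniquely mapped reads were used and that hotspot peaks were H3K4me3 peaks intersected with known hotspots of the dom2 allele of Prdm9 at a reciprocal overlap of 0.2. No note was found for the lists of the Prdm9 mutant, whose columns have the same layout. After duplicate entries of a peak were merged, 10708 wild-type hotspot peaks remained of 10733 lines. A constant column of the hotspot lists was left out.

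Peaks on chromosomes 1 to 19, X and Y were kept. Each library's top 5000 peaks by −log10 p, with ties broken by fold enrichment and then position, were compared, so that list length did not set a share. A peak was called PRDM9-dependent where it overlapped a wild-type hotspot H3K4me3 peak by at least 1 bp, and PRDM9-independent where it overlapped an H3K4me3 peak of the Prdm9 mutant that met no hotspot peak. The chance level of each overlap came from 100 circular shifts of the top peaks along their own chromosomes. Wild-type sites for the recovery measure were merged sites in the top 5000 of both of a pair of wild-type libraries; a wild-type library was scored against the pair it was not in, a mutant library against all 3 pairs. A gained or lost site lay in the top 5000 of every library of 1 group and met no deposited peak of the other.

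The gene table used (RefSeq, GRCm38.p6) gives gene starts and ends but no strand, so start sites could not be read from it. In place of the planned start sites, both ends of each protein-coding gene were taken and those with a Prdm9 mutant H3K4me3 peak within 1000 bp were kept: 20893 ends of 16589 genes. These are called marked gene ends. Coordinates are 1-based on mm10 (GRCm38), and no genome sequence was used here.

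Wild type was compared with the 5 cohesin mutants together by exact two-sided permutation of libraries over 56 splits, whose smallest p is 0.0357, with Benjamini-Hochberg adjustment over 9 tests. Counts of gained and lost sites and the genotype structure were tested by one-sided exact permutation. Wild type against Stag3-/- or Rec8-/- alone gives 10 splits and cannot go below 0.2, so single genotypes are given as values. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between these libraries. Intervals on shares are 95% Wilson intervals and cover counting error only. The measures, tests, alternatives, gene lists and the rule for named sites and genes were fixed before the data were examined, and later choices are marked where they appear. That rule took the 10 best-ranked sites of wild type, of the gained and of the lost set, gene ends gained in all mutants, list genes that differed, and always Stag3, Rec8, Prdm9, Dmc1, Spo11, Psmb9, Hlx, Esrrg, Mid1 and Sts. No group held 4 to 10 libraries, so no library could be tested as an outlier within its genotype.

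Alternatives were the top 2000, top 10000 or all deposited peaks, ranking by fold enrichment, overlap of 50% of a peak or of its summit, autosomes only, 500 bp around gene ends, a −log10 q of at least 5, leaving out each library, a block on the replicate number, and differences within each batch and genotype. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The overlap function disagreed with a direct count for 0 of 300 peaks drawn from the wild-type 1 list. A simulated 20-point difference in the hotspot share of mutants against wild type at 5000 peaks per library was recovered as 20.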

Results

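The DMC1 lists held 12158, 12482 and 11655 peaks in wild-type libraries 1 to 3, 7079 and 21148 in the Stag3-/- libraries, 6853 and 8486 in the Rec8-/- libraries and 8315 in the double mutant. They rested on 403957, 387275 and 5069031 tags in wild type, 1101653 and 822833 in Stag3-/-, 4967736 and 6429397 in Rec8-/- and 5837590 in the double mutant. Mutants differed from wild type by −1722 peaks on average (two-sided exact permutation p = 0.75, adjusted p = 1). At a −log10 q of at least 5, the same libraries held 875, 762 and 11400 peaks in wild type, 2169 and 1566 in Stag3-/-, 6758 and 8355 in Rec8-/- and 8092 in the double mutant, and the difference turned to 1042. Within batches the difference was 1793.5 peaks without input control and −3770 with it, so the count cannot be read as a number of breaks. Any 2 libraries shared 53.5% to 86.1% of their top 5000 peaks, and no 2 lists were copies of each other. The DMC1 peaks do not show the genotype at Stag3 or Rec8: none of the 8 libraries, wild-type ones included, had a peak at an end of either gene.

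The first question was whether breaks stay at PRDM9-designated hotspots when the cohesin subunits are missing. They did in all 8 libraries: 56.7% to 72.4% of the top 5000 peaks lay at wild-type H3K4me3 hotspot peaks, 36.7 to 64.2 times the share of the same peaks shifted along their chromosomes. The share was 67.4% ± 4.80 (SD, n = 3) in wild type, 61.0% ± 6.14 (SD, n = 2) in Stag3-/-, 72.2% ± 0.368 (SD, n = 2) in Rec8-/- and 70.9% in the double mutant. Mutants and wild type differed by 0.048 percentage points, less than the spread between libraries (two-sided exact permutation p = 1). The difference depended on list length, at −3.19 points in the top 2000, 9.79 in the top 10000 and 11.6 over all deposited peaks (p = 0.214, 0.464 and 0.464 by the same permutation). Overlap with any wild-type H3K4me3 peak reached 92.2% ± 5.51 (SD, n = 3) in wild type and 93.3% ± 7.55 (SD, n = 5) in the mutants. Within batches the hotspot difference was −3.96 points without input control and −0.533 with it. At a −log10 q of at least 2, wild-type 1 and 2 held 2931 and 2684 peaks and the Stag3-/- libraries 4263 and 3282. The top 5000 of these lists thus included peaks below that level, whereas every peak of the lists with input control reached it.

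Among the strongest peaks the Stag3 genotypes stood apart. In the top 2000 peaks, the hotspot share was 70.9% ± 0.726 (SD, n = 3) in wild type and 71.0% ± 0.742 (SD, n = 2) in Rec8-/-, against 65.1% ± 0.778 (SD, n = 2) in Stag3-/- and 66.3% in the double mutant. Grouping the libraries by Stag3 was chosen after these values were seen. The 3 libraries that lack Stag3 were then 5.45 points below the 5 that carry it, with no overlap between libraries (two-sided exact permutation p = 0.0357, the smallest possible), and the difference was −5.45 points within the batch without input control and −4.92 within the other. At the planned length of 5000 the same contrast was −5.02 points with overlapping libraries (two-sided exact permutation p = 0.286), so the call depends on list length. At that length the lists without input control take in peaks below a −log10 q of 2, and their effect on this contrast was not tested. Counting instead, in the top 2000, every wild-type H3K4me3 peak that had no peak in the Prdm9 mutant, the difference was −2.08 points.

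**Figure D1:**
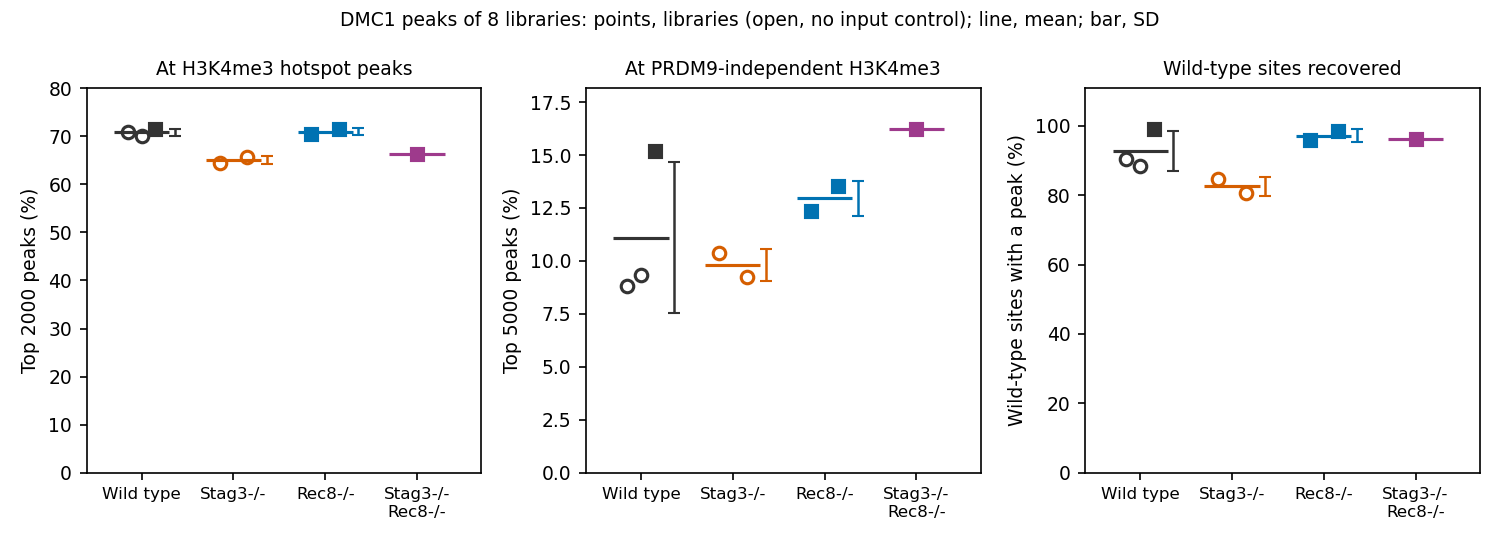
Share of the top 2000 peaks at hotspot H3K4me3 (left), share of the top 5000 peaks at PRDM9-independent H3K4me3 (middle) and share of wild-type sites with a peak (right), in percent, for each library by genotype; open circles, lists without input control; filled squares, lists with input control; lines, means; bars, SD. The left panel places both Stag3-/- libraries and the double mutant between 64.5 and 66.3% and the other 5 libraries between 70.1 and 71.6%.

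Over all top peaks, no genotype had more peaks at H3K4me3 that exists without PRDM9 than the shifted peaks had. PRDM9-independent H3K4me3 held 11.1% ± 3.55 (SD, n = 3) of the top peaks in wild type and 12.4% ± 2.74 (SD, n = 5) in the mutants (two-sided exact permutation p = 0.643). In every library this was below the share of the shifted peaks, at 0.809 to 0.899 times it. Most top peaks lay at hotspot peaks, which the reference peaks of this class do not meet, so a low share was likely from the start. The remaining peaks were not shifted on their own, so an enrichment among them cannot be excluded. Wild-type 3, with the longer peaks of its batch, had 15.2%, and the values with input control were all higher than those without. By the peak summit, the shares were 5.05% ± 0.397 (SD, n = 3) and 5.06% ± 0.643 (SD, n = 5). Within batches the difference was 0.75 points without input control and −1.15 with it.

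Marked gene ends held 2.07% ± 0.752 (SD, n = 3) of the top peaks in wild type, 1.67% ± 0.127 (SD, n = 2) in Stag3-/-, 2.44% ± 0.255 (SD, n = 2) in Rec8-/- and 3.22% in the double mutant, below the shifted level of 2.25% to 3.65% in each case. Here too most top peaks lay at hotspot peaks, so the shifted level cannot exclude an enrichment among the remaining peaks. The mutants and wild type differed by 0.215 points (two-sided exact permutation p = 0.679), and within batches by 0.03 and −0.24. By the summit, the shares were 0.807% ± 0.162 (SD, n = 3) and 0.80% ± 0.117 (SD, n = 5). Rad21, which encodes the mitotic and general counterpart of REC8 in cohesin, had a top peak at a marked end in all 8 libraries. Mcmdc2, required for meiotic strand exchange, had one in all 5 mutants and in 1 wild-type library, but a deposited peak of any rank in all 8, and Ehmt1, a histone methyltransferase gene, in 4 mutants and 2 wild-type libraries.

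The fixed gene lists contained few such genes. Of the 16 break-formation genes with a marked end, 8.75% per library had a top peak in the mutants (Iho1 and Prdm9 in 1 library each, Trip13 in 1, Ehmt1 in 4), higher than 99.3% of random lists of that size, and 6.25% in wild type, higher than 95.6%. This percentile describes these libraries and rests on 4 genes. The 20 cohesin genes stood at 5% in wild type and 5% in the mutants through Rad21 alone, and the 29 strand-exchange and crossover genes at 1.15% and 3.45% through Mcmdc2 alone. No gene of the synaptonemal complex, spermatocyte, spermatid, Sertoli cell, Leydig cell, housekeeping, pseudoautosomal or known-hotspot lists had a top peak at a marked end in any library. No gene end gained a peak in all mutants against wild type, and none of the list genes met the rule for a contrast. At a marked end, Gm10509, Irgm2 and Tmem267 had a top peak in all 5 mutants and in no wild-type library. Each also had a deposited peak of any rank in 1 wild-type library, which the rule for a gain does not allow. Of the genes always looked up, Esrrg and Mid1 had a DMC1 peak inside the gene in all 8 libraries, Prdm9 in 3 mutants and no wild-type library, and Dmc1 in 1 wild-type library and no mutant. Hlx, beside a well-studied hotspot, had a peak within 50 kb in 3 wild-type and 3 mutant libraries and Spo11, the gene of the break-forming enzyme, in none. Stag3 had one within 50 kb in 3 wild-type and 2 mutant libraries, Rec8 in 1 and 3, and Psmb9, which lies at a classical hotspot, in 1 and 1. Sts was missing from the gene table.

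The next question was how far the mutants used the same sites as wild type. Sites shared by a pair of wild-type libraries (3118 to 3753 sites) carried a deposited peak in 92.6% ± 5.74 (SD, n = 3) of cases in wild type, 82.6% ± 2.75 (SD, n = 2) in Stag3-/-, 97.2% ± 1.82 (SD, n = 2) in Rec8-/- and 96.1% in the double mutant. Mutants and wild type did not differ beyond the spread (−1.46 points, exact permutation p = 0.821). Within batches the difference was −6.71 points without input control and −2.31 with it. Leaving out Stag3-/- 1 or Stag3-/- 2 turned the pooled difference to 0.184 and 1.16. A −log10 q of at least 5 turned it to 27.3 points and an overlap of 50% to 4.56 (p = 0.286 and 0.607 by the same permutation). Libraries of 1 genotype shared 3625 top sites on average over 5 pairs, against 3446 over 23 pairs of different genotypes (one-sided exact permutation p = 0.165, adjusted p = 0.496); in the top 2000 the difference was 200.5 sites and p = 0.0321 by the same permutation. The closest pair was Rec8-/- 1 and 2 with 4304 shared sites, and each Stag3-/- library shared most with the double mutant (3989 and 3559). The 2 Stag3-/- libraries shared 3316, fewer than Stag3-/- 1 shared with wild-type 3 (3458), Rec8-/- 1 (3508) or Rec8-/- 2 (3455).

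No site was gained in all 5 mutants against wild type; at a list length of 10000 there were 2, and without wild-type 3, the deepest wild-type library, 72 (p = 0.0476 by the same permutation). Sites lost in all mutants numbered 8 (one-sided exact permutation p = 0.0357, adjusted p = 0.161), and all 8 lay on the X chromosome. They included X:7299820-7302834 inside Clcn5, X:71220848-71223287 inside Mtm1 and X:84888069-84891043 inside Dmd, the dystrophin gene. Another, X:11856100-11858736, lay outside genes, 178001 bp from Bcor, the nearest protein-coding gene. Of the 8, 7 overlapped hotspot H3K4me3 and none met an H3K4me3 peak of the Prdm9 mutant. The 8 sites ranked between 1221 and 4912 in the wild-type lists, so none was among the strongest peaks, and the count was 0 in the top 2000 and 73 in the top 10000 (p = 0.0893 by the same permutation). Leaving out a library gave 8 to 22 sites, and p stayed at or below 0.05 only without Stag3-/- 1: there were 12, 15 and 22 sites without wild-type 1, 2 and 3, 8 without Stag3-/- 2, 9 and 21 without Rec8-/- 1 and 2, and 10 without the double mutant.

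The X chromosome, which has no homologue over most of its length in males, held a smaller share of peaks in every mutant library than in any wild-type library. It held 7.95% ± 0.310 (SD, n = 3) of the top 5000 peaks in wild type, 5.53% ± 0.410 (SD, n = 2) in Stag3-/-, 4.57% ± 0.382 (SD, n = 2) in Rec8-/- and 5.66% in the double mutant. The highest mutant value, 5.82%, was below the lowest wild-type value, 7.64%. The difference of −2.78 points had the smallest p the design allows (two-sided exact permutation p = 0.0357) and an adjusted p of 0.161, so it failed the correction. It was −2.27 points within the batch without input control and −3.33 with it. In the top 2000 peaks the contrast was larger, at 12.9% ± 0.645 (SD, n = 3) against 6.49% ± 0.584 (SD, n = 5), 1.99 times, whereas over all deposited peaks it was −0.979 points (two-sided exact permutation p = 0.179).

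All 10 sites with the best mean rank over the wild-type lists were on the X, 8 of them at hotspot H3K4me3, and 6 lay inside a gene. Examples are X:42213503-42218775 and X:42259486-42264317, both inside Stag2, the gene of a general cohesin subunit, X:166533816-166539359 inside Egfl6 and X:52951605-52956924 inside Phf6. They ranked from 1 to 19 in the wild-type lists; as they were chosen by these ranks, their ranks in the mutant lists say nothing on a difference. Of the 10 best-ranked sites over the 5 mutants (a choice made after the data were seen), 2 were on the X. The others included 2:38134913-38140457 inside Dennd1a, 6:39637711-39643648 inside Braf, a kinase gene, and 9:83857301-83863181 inside Ttk, a spindle checkpoint kinase gene. All 10 were also top peaks in every wild-type library.

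**Figure D2:**
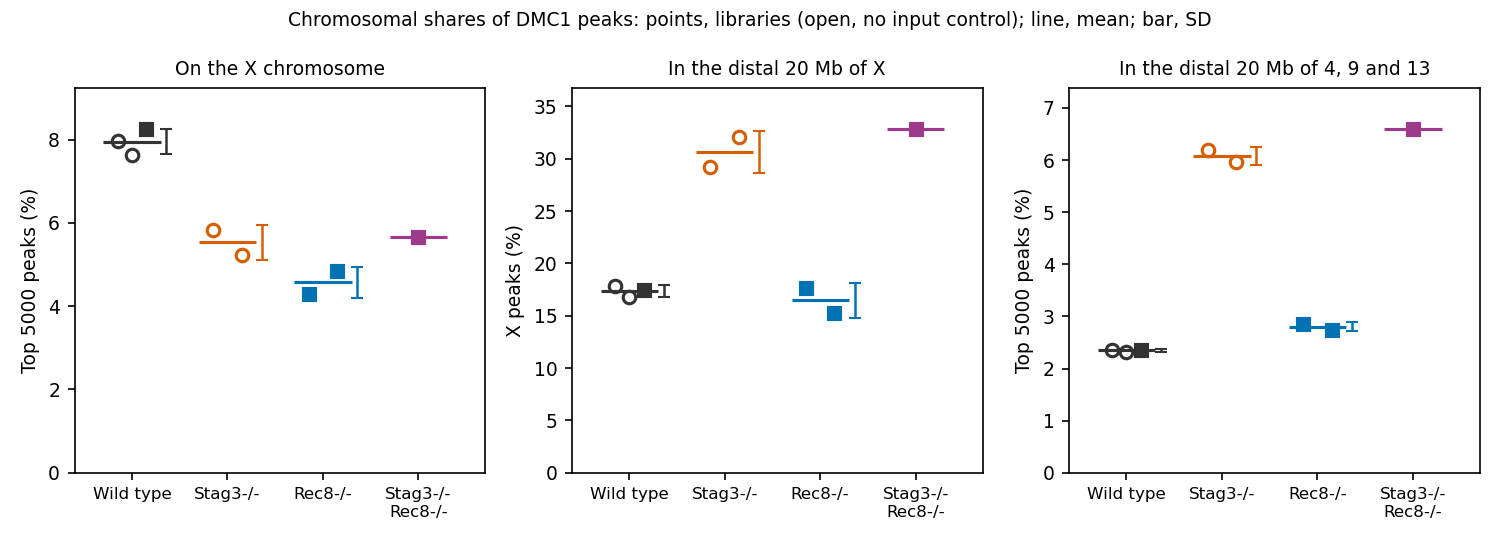
Share of the top 5000 peaks on the X chromosome (left), share of a library's X peaks in the distal 20 Mb of X (middle) and share of the top 5000 peaks in the distal 20 Mb of chromosomes 4, 9 and 13 together (right), in percent, per library and genotype; symbols, lines and bars as for hotspot use. All 5 mutants sit below wild type on the X, and the 3 libraries without Stag3 stand above the other 5 in the middle and right panels.

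The libraries without Stag3 also differed from the others in where top peaks lay along chromosomes. These are shares of ranked DMC1 peaks, and whether breaks formed elsewhere or lasted longer there was not tested. In the libraries without Stag3, the distal 20 Mb of chromosome 9 held 2.49% ± 0.147 (SD, n = 3) of the top peaks against 0.836% ± 0.141 (SD, n = 5) in the libraries with Stag3, those of chromosome 13 held 2.23% ± 0.110 (n = 3) against 0.952% ± 0.0901 (n = 5), and those of chromosome 4 held 1.53% ± 0.110 (n = 3) against 0.74% ± 0.0735 (n = 5). These 3 ends together held 2.35% ± 0.0231 (SD, n = 3) in wild type, 2.80% ± 0.0849 (SD, n = 2) in Rec8-/-, 6.08% ± 0.170 (SD, n = 2) in Stag3-/- and 6.60% in the double mutant, a 2.47-fold difference by Stag3 (two-sided exact permutation p = 0.0357, the smallest possible). Within batches this difference by Stag3 was 3.74 points without and 3.95 points with input control. Both Rec8-/- libraries (2.86 and 2.74%) also lay above every wild-type library (2.32 to 2.36%), by far less than the libraries without Stag3. Wild type against all 5 mutants therefore gave the same p (2.53 points, two-sided exact permutation p = 0.0357). The contrast by Stag3 and the choice of these ends were made after the values were seen.

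Other stretches held smaller shares, as they must in part when shares of a fixed number of peaks are compared. Window 90 to 100 Mb of chromosome 15 held 0.0533% ± 0.0115 (SD, n = 3) of the top peaks without Stag3 and 0.592% ± 0.0996 (SD, n = 5) with it. Windows 80 to 90 Mb of chromosome 16 (0.173% against 0.464%) and 110 to 120 Mb of chromosome 10 (0.193% against 0.492%) were lower as well. Over the genome, 106 of 275 windows of 10 Mb had no overlap between libraries with and without Stag3. Of these, 52 were higher and 54 lower without it. For a split fixed in advance, 9.82 windows would be separated by chance, but this split was chosen after the values were seen. Some whole chromosomes differed as well: chromosome 9 held 7.75% ± 0.223 (SD, n = 3) against 4.63% ± 0.277 (SD, n = 5), chromosome 13 held 6.97% ± 0.214 (n = 3) against 4.50% ± 0.331 (n = 5), and chromosome 15 held 3.19% ± 0.15 (n = 3) against 4.54% ± 0.314 (n = 5). Chromosome 4 did not separate as a whole (5.81% ± 0.197, n = 3, against 5.83% ± 0.608, n = 5; two-sided exact permutation p = 0.929), nor did chromosome 6 (5.85% ± 0.272, n = 3, against 5.47% ± 0.421, n = 5; p = 0.25 by the same permutation). Chromosomes 3, 10, 16, 18 and 19 were also lower in every library without Stag3 than in any with it. These and chromosomes 9, 13 and 15 each had a two-sided exact permutation p of 0.0357 and an adjusted p of 0.0893 over 20 chromosomes.

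The X chromosome, split at its distal 20 Mb after the data were seen, showed both patterns at once. Outside its distal 20 Mb it held 6.57% ± 0.232 (SD, n = 3) of the top peaks in wild type and 3.82% ± 0.281 (SD, n = 5) in the mutants, with nearly equal means of 3.84, 3.82 and 3.80% in Stag3-/-, Rec8-/- and the double mutant. The distal 20 Mb took 17.3% ± 0.548 (SD, n = 3) of X peaks in wild type and 16.5% ± 1.69 (SD, n = 2) in Rec8-/-, but 30.6% ± 2.02 (SD, n = 2) in Stag3-/- and 32.9% in the double mutant. As a share of all top peaks, this stretch held 1.38% in wild type, 1.69% in Stag3-/-, 1.86% in the double mutant and 0.75% in Rec8-/-, so most of the contrast between Stag3-/- and wild type within X comes from the lower share of its remainder. Beyond Mid1, the gene that spans the border of the pseudoautosomal region, each wild-type library had 1 deposited peak and no mutant library had any.

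**Figure D3:**
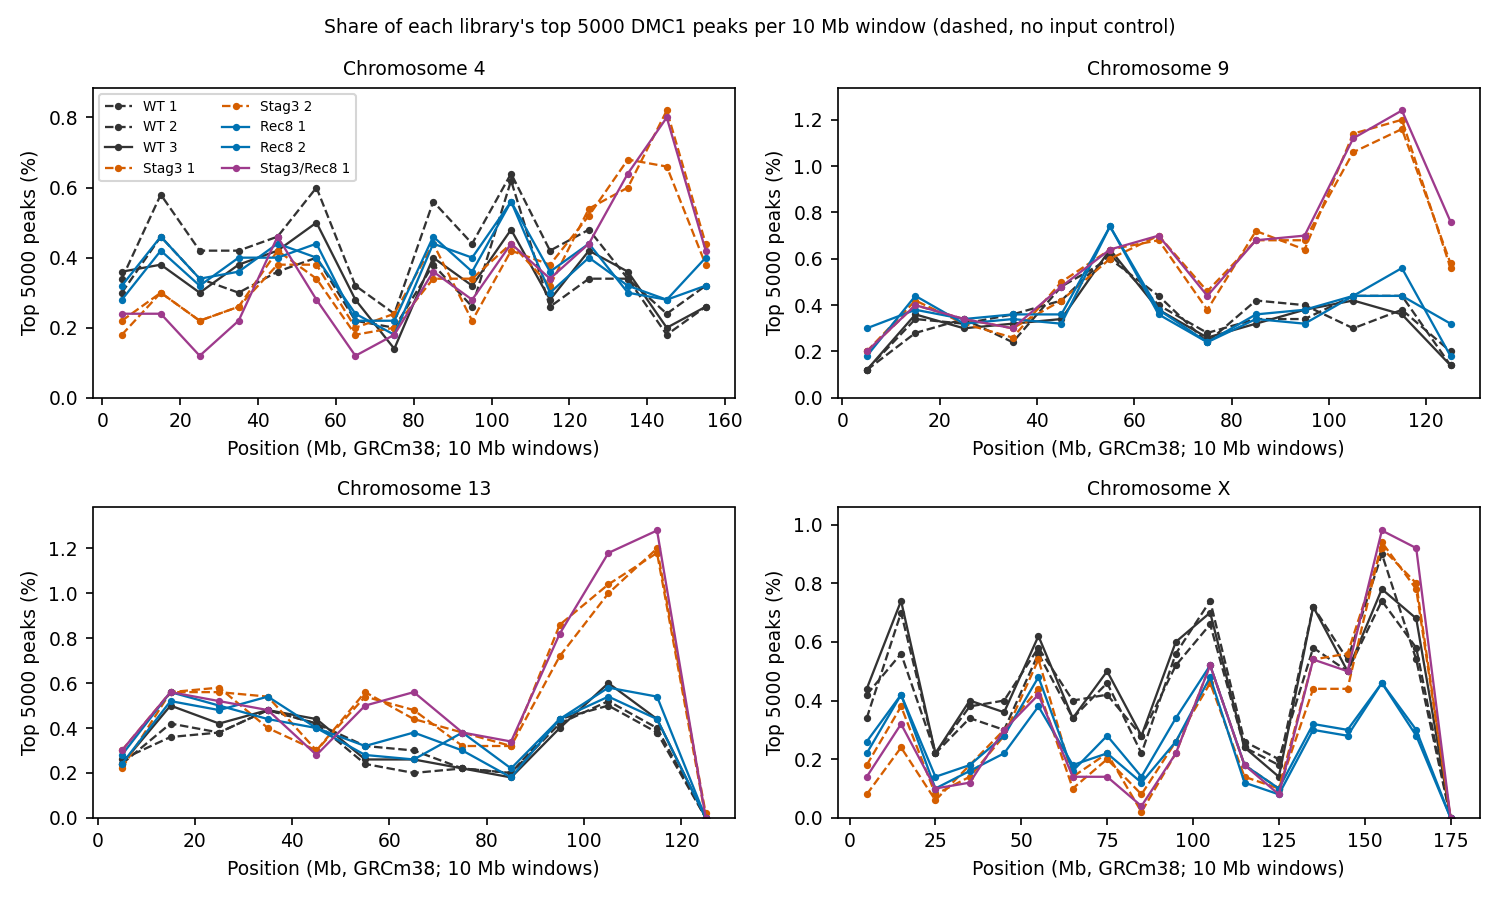
Percent of each library's top 5000 peaks in successive 10 Mb windows (horizontal axis, Mb on GRCm38) of chromosomes 4, 9, 13 and X, 1 line per library coloured by genotype, dashed for lists without input control. The lines of the 3 libraries without Stag3 rise toward the distal end of chromosomes 9 and 13, reaching 1.2 and 1.22% on average in the window from 110 to 120 Mb, where the other 5 average 0.436 and 0.44%.

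**Figure D4:**
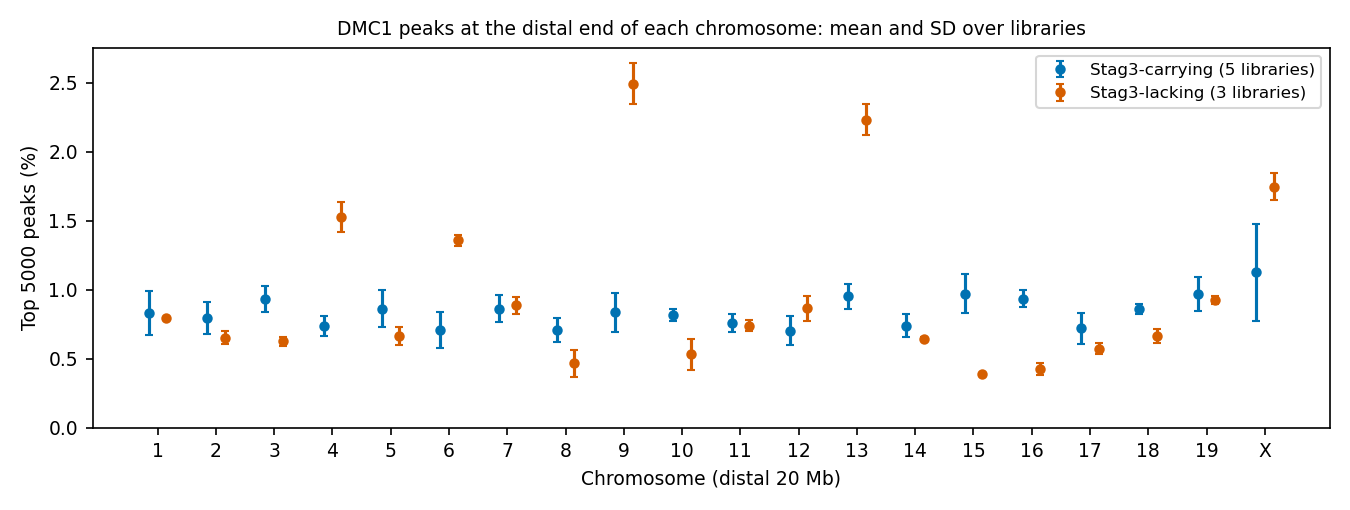
Percent of the top 5000 peaks in the distal 20 Mb of each chromosome, mean and SD over the 3 libraries without Stag3 and the 5 libraries with it. The ends of chromosomes 4, 6, 9, 13 and X are higher without Stag3 in every library, and those of 3, 8, 10, 14, 15, 16 and 18 lower.

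At single sites, 34 were gained in the libraries without Stag3 and met no peak of the 5 others (one-sided exact permutation p = 0.0179). Another 14 were lost (same p). The contrast by Stag3 was chosen after the values were seen, so these p-values cannot exclude chance. Of the 34, 9 were on chromosome 9, 7 on chromosome 4, 5 on chromosome 6 and 3 on chromosome 13. Hotspot H3K4me3 was overlapped by 22 of them (64.7%, Wilson interval 47.9 to 78.5%) and some wild-type H3K4me3 peak by 31. PRDM9-independent H3K4me3 was met by 6 (17.6%, 8.35 to 33.5%) and a marked gene end by 4 (11.8%, 4.67 to 26.6%). Among sites in the top 5000 of all 8 libraries, these shares were 20% and 3.54%. The best ranked gained site was 7:145327703-145330892, at the end of chromosome 7 near Mrgprd. It was followed by 6:148830973-148834256 at a marked end of Ipo8, 9:107531660-107535105 across Tmem115 and 4:139317964-139321754 across Akr7a5. Lost sites included 18:80662047-80664961 inside Nfatc1, a transcription factor gene, and 15:93336612-93339348 at Yaf2. Gained sites numbered 4 in the top 2000 and 61 in the top 10000 (p = 0.107 by the same permutation), and 52, 60 and 65 without Stag3-/- 1, Stag3-/- 2 and wild-type 3. Lost sites numbered 0 and 94 at those lengths (the latter with p = 0.0714 by the same permutation), and 140 without the double mutant, 32 without wild-type 2, and 23 without wild-type 1 or Stag3-/- 2. Without Stag3-/- 1 there were 18, and in that setting and those without wild-type 1 or Stag3-/- 2 the permutation p was above 0.05.

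The H3K4me3 lists show what PRDM9 contributes at these sites. Of 10708 wild-type H3K4me3 hotspot peaks, 555 (5.18%, Wilson interval 4.78 to 5.62%) overlapped any H3K4me3 peak of the Prdm9 mutant, against 81.6% (81.4 to 81.9%) of the 82879 other wild-type peaks. With an overlap of 50% of the wild-type peak, 104 hotspot peaks (0.971%) remained. The authors' own hotspot list of the mutant has 353 peaks, 30.3 times fewer than that of wild type, although the mutant's full list is the longer (107732 against 93587 peaks). Hotspot peaks in the highest quartile of the hotspot score kept a mutant peak in 8.22% of cases (7.24 to 9.32%), those in the lowest in 3.7% (3.05 to 4.48%). There is 1 list per genotype, so no test was made.

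The stronger the H3K4me3 at a hotspot in wild type, the more often a DMC1 peak was found there, in every genotype. In wild type, 20.3% ± 12.9 (SD, n = 3) of hotspots in the lowest quartile of H3K4me3 score and 83.6% ± 12.4 (SD, n = 3) in the highest carried a DMC1 peak. The corresponding values were 7.28% ± 1.16 and 79.9% ± 3.28 (SD, n = 2) in Stag3-/-, 13% ± 5.57 and 92.0% ± 2.77 (SD, n = 2) in Rec8-/- and 12.7% and 96.5% in the double mutant. The gap between the quartiles was 63.2 points ± 0.607 (SD, n = 3) in wild type and 77.4 ± 5.46 (SD, n = 5) in the mutants; it was not tested, since the share of weak hotspots with a peak depends on depth and list length.

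**Figure D5:**
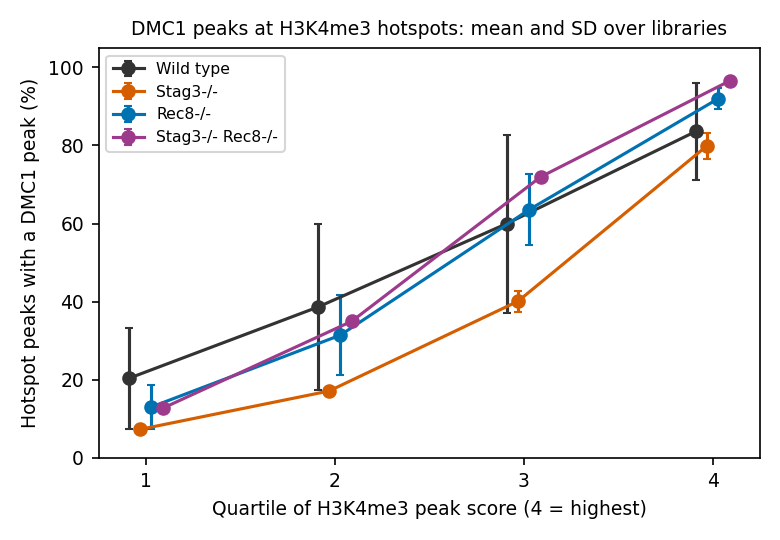
Percent of wild-type H3K4me3 hotspot peaks with a deposited DMC1 peak (vertical axis) by quartile of H3K4me3 peak score (horizontal axis, 4 highest), mean and SD over the libraries of each genotype; the double mutant has 1 library and no bar. Every genotype rises from 20.3% or less in the lowest quartile to 79.9% or more in the highest.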

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

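Except for the comparison of the X share with hotspot H3K4me3, the tests in this part were chosen only after the results they bear on were seen. The test outside windows higher without Stag3 had its prediction written beforehand. It nevertheless rests on a grouping and on windows that were chosen after the values were seen.

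For 3 of 34 values looked at, Stag3-/- libraries all lay on 1 side of the wild-type mean and Rec8-/- libraries on the other. This held for the mean of all wild-type libraries and for that of the batch. Single wild-type libraries overlapped them, with 1 exception. On chromosome 7 both Rec8-/- libraries (5.02 and 4.94%) lay above every wild-type library (4.64, 4.44 and 4.40%). Stag3-/- minus Rec8-/-, each relative to its batch, was −1.45 points for the share of peak summits at PRDM9-independent H3K4me3 in the top 5000, −0.32 points for the share of top peaks on chromosome 2 and −0.78 points for that on chromosome 7. These differences were not tested, and with so many values some would arise by chance.

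Top peaks at the distal ends of chromosomes 4, 9 and 13 were 2.47 times as frequent without Stag3. The tables argue against a processing difference, since the smaller within-batch difference was 3.74 points at a pooled SD of 0.0963. Chromosome 5, which holds Stag3, had 2 of 48 gained and lost sites (4.17%), so most of these sites do not lie in DNA of another strain carried along beside Stag3. An effect of such DNA on other chromosomes, or strain DNA elsewhere, was not tested. The split by Stag3 separated 106 windows and was the highest, 1 of 56 (next, wild type against all mutants, 38), but it was chosen after the values were seen, so this count cannot exclude chance. Weak peaks away from H3K4me3, a stand-in for copy number, were no denser at these ends in Stag3-/- 2 (0.993 times wild type, 0.874 to 1.13). In Stag3-/- 1 the interval was wide (1.14 times, 0.639 to 2.01), and the double mutant has no such peaks. Peaks were called over their local background, which a gain in copy number would also raise. How far the number of weak peaks follows copy number was not tested, so a gain stays open in every library without Stag3. A candidate explanation is that breaks build up near repeat arrays called mo-2, known to gather break-forming proteins at the distal ends of 4, 9, 13 and the X: these 4 ends ranked no lower than 5 among 20, but chromosome 6 ranked 4, the last 5 Mb of the 16 other chromosomes together were also 1.87 times as high without Stag3, and the arrays were not located, so this stays undecided.

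Top peaks on the X were fewer in every mutant. The batches do not explain this, as the within-batch difference nearer to 0 was −2.27 points. Depth stays open. Rec8-/- 1, with fewer tags than wild-type 3, was −3.96 points from it, but the 4 other mutant libraries had more tags than the wild-type libraries of their batch. The library with more tags had the higher X share in Stag3-/- (5.82 against 5.24%) and Rec8-/- (4.84 against 4.3%), at a pooled SD of 0.356 points. Wild-type 3 (8.26%) was also above wild-type 1 and 2 (7.96 and 7.64%), but it stands in the other batch. These pairs therefore cannot settle the role of depth. Chance cannot be excluded for the 8 lost sites once the tests are adjusted (p = 0.161): 2 of 56 splits lost at least as many, the other being the split by Stag3 with 34, which points to the structure described above, and leaving out any single library except Stag3-/- 1 raised the unadjusted permutation p above 0.05. If autosomal breaks lasted as long in mutants as X breaks do, the X share could fall toward that of hotspot H3K4me3 peaks, 3.50% (3.17 to 3.87%); the mutants lay 1.67 points above it and wild type 4.45, which leaves the hypothesis undecided, and the mix of spermatocyte stages was not tested.

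The hotspot share of the top 2000 was lower without Stag3. Breaks moving into windows with fewer listed hotspots are not the whole source, since 114% of the difference remained outside the windows that were higher without Stag3. These windows were picked from the same data, and the share outside them does not measure what a move into them adds. Such a move therefore stays open as a part of the lower hotspot share. Breaks at H3K4me3 that does not need PRDM9 could also lower it, and the measures differ: by overlap of 1 bp, as used for the hotspot share, PRDM9-independent H3K4me3 held 14.85 and 13.75% in Stag3-/- against 10.85 and 10.75% in wild-type 1 and 2, and 20.85% in the double mutant against 17.25, 16.15 and 16.5% in the other libraries with input control. By summit it held 6.73% ± 0.431 (SD, n = 3) without and 6.90% ± 0.893 (SD, n = 5) with Stag3, a difference of −0.167 (0.525 and −0.883 within batches), so this stays open. A biological role of STAG3 in the choice of hotspots remains untested.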

How the results depend on the processing

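Alternatives in the Stag3 contrasts and a −log10 q of at least 2 were chosen after the data were seen. So were the H3K4me3 peaks with no Prdm9 mutant peak and the X share without its distal 20 Mb. Of 216 settings, 43 lost a call, 2 gained it, and 30 had the opposite sign, 7 of these without a test and within 1 SD of the main value; where a value changed, the cause was not tested unless stated. The labels do not say that equal replicate numbers pair libraries, and the correlations of same-numbered libraries, from −0.0751 to 0.0845, gave no sign of it.

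With a −log10 q of at least 5, the difference in peaks turned to 1042 and that in recovery to 27.3, the gap between H3K4me3 quartiles was 51.1, and 1 gained and 9 lost sites were found; at least 2 gave 483 peaks. In the top 2000 the hotspot difference was −3.19 (9.79 in the top 10000 and 11.6 over all deposited peaks), the genotype structure 200.5, and there were 0 lost sites, 4 gained and 0 lost without Stag3. The top 10000 gave 2 gained and 73 lost sites, 61 gained and 94 lost without Stag3, and 70 windows; the top 5000 gave a quartile gap of 69.2. Over all deposited peaks the X difference was −0.979. Ranking by fold enrichment gave −1.63 for hotspots. With 50% overlap, the difference was −0.679 for PRDM9-independent sites, −0.0413 for gene ends (−0.00667 by summit) and 4.56 for recovery, and 0.971% of hotspot peaks met a Prdm9 mutant peak; the genotype structure cannot move under this setting.

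Against wild type, Stag3-/- differed by 2015 peaks, −6.40 for hotspots, −1.30 for PRDM9-independent sites, −0.403 for gene ends, −2.42 for the X and −9.97 for recovery, Rec8-/- by −4429 peaks, 4.78 for hotspots, −3.38 for the X and 4.57 for recovery, and the double mutant by −3783 peaks, 5.13 for PRDM9-independent sites, 1.15 for gene ends, −2.29 for the X and 3.51 for recovery. Within the batch without input control, peaks differed by 1793.5, hotspots by −3.96, the X by −2.27 and recovery by −6.71; with it, hotspots by −0.533, PRDM9-independent sites by −1.15, gene ends by −0.24, the X by −3.33 and the distal ends of 4, 9 and 13 by 3.95.

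With the replicate block, the X difference was −2.65 (smallest possible permutation p 0.167), that of the distal ends 3.61 (smallest 0.111), recovery 1.54, peaks −1204, hotspots 1.96, PRDM9-independent sites 3.13 and gene ends 0.617; fewer splits end the first 2 calls by construction.

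Leaving out each library gave −4415 to −841 for peaks (−4415 without Stag3-/- 2), −2.31 to 2.75 for hotspots, 0.092 to 3.29 for PRDM9-independent sites, −0.022 to 0.648 for gene ends, −2.94 to −2.56 for the X, −3.29 to 1.16 for recovery (no value without a wild-type library), 61.1 to 269 for structure, 3.55 to 3.87 for the distal ends and −5.85 to −4.98 for the hotspot share of the top 2000 without Stag3. For the X, the distal ends and this hotspot share, the smallest possible p is then 0.0571 or 0.0952, so no call was possible. Gained sites ranged from 0 to 72 (72 without wild-type 3), lost sites from 8 to 22 (22 without wild-type 3, 21 without Rec8-/- 2, 15 without wild-type 2), gained sites without Stag3 from 34 to 65 (65 without wild-type 3, 52 and 60 without Stag3-/- 1 and 2), lost sites without Stag3 from 16 to 140 (140 without the double mutant, 32 without wild-type 2, 23 without wild-type 1 or Stag3-/- 2), and windows from 108 to 133. Calls of lost sites ended without any single library except Stag3-/- 1, and those of lost sites without Stag3 ended without wild-type 1, Stag3-/- 1 or Stag3-/- 2. Depth limits the lists without input control: with 387275 to 1101653 tags, absence of a peak there is weak evidence of absence of breaks.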

Other observations

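The tests of windows in this part were chosen after the data were seen. Gains without Stag3 were not limited to chromosomes 4, 9, 13 and X. In the last 5 Mb, 11 of 20 chromosomes were higher in every library without Stag3 than in any with it (1, 3, 6, 7, 9, 10, 12, 13, 17, 18 and 19) and none was lower. For the 16 chromosomes other than 4, 9, 13 and X together, the last 5 Mb held 4.53% ± 0.130 (SD, n = 3) of the top peaks without Stag3 and 2.42% ± 0.359 (SD, n = 5) with it (two-sided exact permutation p = 0.0357, the smallest possible). In this stretch both Rec8-/- libraries (2.58 and 2.98%) also lay above every wild-type library (2.14 to 2.2%). The last 10 Mb of these 16 chromosomes held 6.29% ± 0.0306 (n = 3) against 6.02% ± 0.448 (n = 5; p = 0.429 by the same permutation) and their last 20 Mb 11.2% ± 0.209 (n = 3) against 13.2% ± 0.676 (n = 5; p = 0.0357). On 4, 9, 13 and X together the last 5, 10 and 20 Mb were 2.13, 2.27 and 2.19 times as high without Stag3, but in the last 5 Mb only chromosomes 9 (3.57 times) and 13 (2.61 times) of the 4 separated: chromosome 4 held 0.287% ± 0.0306 (n = 3) against 0.256% ± 0.0498 (n = 5; two-sided exact permutation p = 0.429) and X 0.32% against 0.208% (p = 0.0714 by the same permutation). The window 140 to 150 Mb of chromosome 6 held 0.933% ± 0.0306 (SD, n = 3) of the top peaks without Stag3 and 0.38% ± 0.0648 (SD, n = 5) with it. Window 170 to 180 Mb of chromosome 1 held 0.767% ± 0.0115 (n = 3) against 0.392% ± 0.0832 (n = 5), while the next window, 180 to 190 Mb, went the other way at 0.26% ± 0.0200 (n = 3) against 0.548% ± 0.0856 (n = 5). On chromosome 15 the windows from 0 to 10 Mb (0.153% against 0.404%) and 10 to 20 Mb (0.187% against 0.40%) were lower without Stag3, whereas its last window, from 100 Mb, did not separate (0.12% against 0.076%). Chromosome 18 held 2.76% ± 0.164 (SD, n = 3) of the top peaks without Stag3 and 3.67% ± 0.0832 (SD, n = 5) with it.

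Outside their distal 20 Mb, chromosomes 9 and 13 were still 1.38 and 1.33 times as high without Stag3, whereas chromosome 4 stood at 0.841 times. A few hotspot scores in the mutant's hotspot list exceeded every score in the wild-type list: 2 of its 353 peaks did, and its highest score was 91661 against 8973.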
